A study of Homo sapiens with 6 samples.

How the data were processed

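Primary fibroblasts from the upper lobe of the lung of 3 patients with idiopathic pulmonary fibrosis and 3 healthy controls were grown in medium with 10% serum and used at passage 3 or 4, per the labels. ATAC-seq was run on each culture. Groups and replicate numbers were taken from the sample titles. Donors of the 2 groups were different people, so shared numbers pair no samples, and each p-value on sample means measures the spread between donors.

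The authors deposited a list of broad peaks for each sample. Reads were aligned with Bowtie2 and peaks were called with MACS2 on hg38, per the submitters' processing notes, which give no versions. Trimming, removal of duplicates and shifting of reads for the transposase are not given in the sources used here, and any of these can change peak edges and weak peaks. Each list was called per sample, and no pooled list was used here. The authors' MACS2 output gives each peak a whole-number display score, which equalled 10 times the −log10 q. The deposited lists also give each peak's fold enrichment, a linear ratio over the caller's background estimate. The −log10 p and −log10 q of each peak were computed by the authors' caller and deposited with it. Fold, −log10 p and −log10 q were used mainly to rank peaks within their own list. A single −log10 q limit for all lists served in the stricter alternative and in the description of Healthy 1 below. Such a limit depends on depth, as does fold. The files hold no read counts, so depth per sample is unknown and no interval for counting error can be given. A list's length moves with depth and signal quality as well as with accessibility. All lists had a shortest peak of 73 bp and a −log10 q down to about 1. Healthy 1 stood apart, with 51.6% of its peaks at that shortest width, 6 peaks with a −log10 q of at least 5 (3011 to 30448 in the other lists), and 18 peaks on unplaced or mitochondrial sequences, of which the other lists held 0.

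Only the 22 autosomes were analysed. Gene positions and symbols came from a RefSeq gene table of GRCh38.p14, which shares its primary chromosomes with hg38, and 19126 autosomal protein-coding genes were used. The table gives gene intervals with neither strand nor transcripts. The planned promoter windows were therefore replaced by windows of 1 kb on either side of both annotated ends of a gene, called gene ends, which may be 5′ or 3′ ends. Regions were assigned to the nearest protein-coding gene interval within 100 kb, in place of the nearest transcript start. Exons, introns and untranslated parts were not told apart. A search for 30 transcription factor motifs was planned and not run, because no genome sequence was used here.

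For each sample the number of peaks, the covered length, the share of peaks at a gene end and the number of genes with such a peak were computed, and group means were compared by exact two-sided permutation of the 6 samples. Overlap of samples was measured by the Jaccard index of covered base pairs. Peaks of all samples that overlapped by at least 1 bp were merged into regions. A region was IPF-only when all IPF lists and no Healthy list had a peak in it, and Healthy-only in the reverse case. Expected numbers came from a model in which, among regions found in a given number of lists, the chance of each combination is proportional to the product of 1 weight per sample fitted to the list lengths. Intervals are 95% percentile intervals over 200 bootstrap draws of chromosomes. The samples were held fixed in these draws, so no such interval measures variation between donors or libraries. On regions simulated from the fitted model itself, without group effects, the ratio of observed to expected averaged 0.998 (0.961 to 1.03 over 20 simulations). That value follows from the design and does not show that the real lists obey the model. With 1000 group-only regions added, the ratio averaged 1.21 and the excess 722, so the model understates an excess.

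Equal list length was set by keeping the peaks with the highest −log10 q, 4887 in all 6 lists, or 42514 in the 5 lists other than Healthy 1. Regions per gene were compared with background regions, those with a peak in at least as many lists as the group has, by a one-sided binomial test over genes with at least 5 background regions, adjusted by Benjamini-Hochberg. For 18 gene lists (extracellular matrix, contractile, TGF-beta and BMP, WNT, lung mesenchyme transcription factors, HOX, cytokines, senescence, proteases, prostaglandin, growth factors, housekeeping, epithelial, endothelial, immune, mesothelial, pericyte and genes of other organs; 365 entries), group-only regions were compared with those of 10000 random gene lists matched on background regions. Simulated lists with no excess were called in 0% of cases.

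Groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the 10 genes with end peaks in all samples of one group and none of the other that ranked highest by peak fold in their lists. It also named the 10 genes with the most group-only regions, and per list up to 4 members whose end peaks differed by at least 2 samples and up to 4 with the most group-only regions. The rule for regions was applied again to the lists of equal length. The binomial scan and 3 alternatives were added later: joining regions across gaps of 500 bp, Healthy 4 as the sole control, and peaks in the upper part of their list. Other alternatives were a −log10 q of at least 5, equal lengths, leaving out each sample, replicate numbers 1 and 2 only, regions at least 50% covered, bins of 500 bp, 2 of 3 samples, windows of 2.5 and 0.2 kb, a distance of 20 kb, a background of regions in exactly 3 samples, and overlap scaled to the shorter list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

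For the gene with the most IPF-only regions, Healthy 2 and Healthy 4 were left out in turn. The share of the resulting IPF-only regions in which the left-out sample had a peak was compared with the share in IPF-only regions of all genes of similar strength, by decile of the lowest IPF percentile by −log10 q. These tests were chosen after the results had been seen.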

Results

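Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in fibroblasts grown from the upper lobes of human lungs. Fibroblasts are the cells that make and remodel the connective tissue of the lung. The 6 samples came from separate donors and formed 2 groups. The IPF group held 3 cultures from patients with idiopathic pulmonary fibrosis, a progressive scarring disease, and was named IPF 1, 2 and 3. The Healthy group held 3 control cultures, named Healthy 1, 2 and 4. The design compared the groups to find regions that differ in accessibility. Read depth is unknown, because the files give peaks and no read counts. The lists held 78730, 124631 and 89131 autosomal peaks in IPF 1, 2 and 3, and 4887, 42514 and 104501 in Healthy 1, 2 and 4.

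Few genes had a peak near an end in every sample, as the shortest list limits their number. Of 363 genes on 18 lists fixed in advance, 17 had a peak within 1 kb of a gene end in all 6 samples. These were TAGLN, COL1A2, SPARC, LOXL1, LOXL2, TEAD1, FGF2, MET, SMAD4, FZD2, CCL20, LMNB1, HMGA2, PTGER2, RGS5 and the housekeeping genes EEF1A1 and LTAP1. The collagen gene COL1A2 was thus among them, while the matrix gene POSTN and the muscle gene MYH11 had no end peak in any sample. A further 124 had one in the 3 IPF samples and in 2 of the 3 Healthy samples, and 95 had none in any sample. Over all 19126 autosomal protein-coding genes, 1896 carried a peak at an end in every sample, 7673 in the 3 IPF and 2 Healthy samples, and 5288 in none.

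Peaks were more numerous in IPF lists on average, but the groups overlapped. The mean was 97497 ± 24067 peaks in IPF and 50634 ± 50301 in Healthy (SD, n = 3 each, exact two-sided permutation p = 0.3). The smallest p that 3 against 3 samples allow is 0.1. Peaks covered 24.9 ± 7.48 Mb in IPF and 12.2 ± 13.6 Mb in Healthy (SD, n = 3 each, exact permutation p = 0.3). A peak lay at an end of 12441 ± 652 genes in IPF and of 8185 ± 5595 genes in Healthy (SD, n = 3 each, exact permutation p = 0.3). The share of peaks at a gene end was 14.1 ± 2.04% in IPF and 22.98 ± 10.2% in Healthy (SD, n = 3 each, exact permutation p = 0.3). These differences (IPF minus Healthy) of 46863 peaks, 12.6 Mb, 4256 genes and -8.84 percentage points depended on single Healthy samples. Without Healthy 1 they were 23990 peaks, 6.82 Mb, 1134 genes and -3.53 points, and without Healthy 4 they were 73797 peaks, 20.1 Mb, 6536 genes and -13.7 points. When the 5 other lists were limited to their 42514 strongest peaks each, the number of genes with a peak at an end was lower in IPF than in Healthy. It was 9252 ± 318 in IPF (SD, n = 3) and 9586 on average in Healthy 2 and 4 (exact permutation p = 0.4). The share of peaks at a gene end was then 20.2% in IPF and 21.1% in Healthy, a difference of -0.917 points, and covered length differed by 1.93 Mb.

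**Figure D1:**
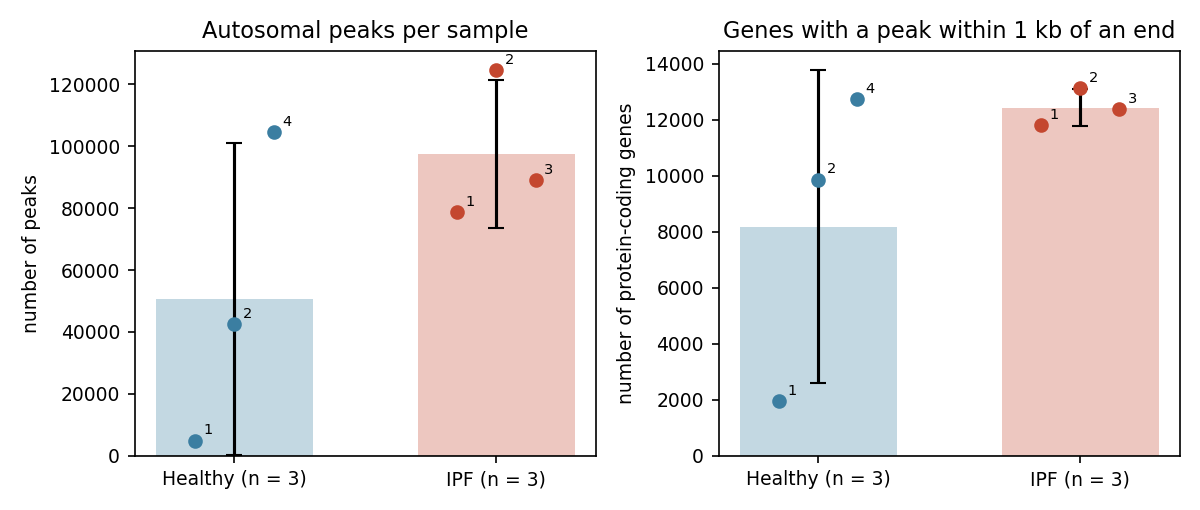
Autosomal peaks per sample (left, number of peaks) and protein-coding genes with a peak within 1 kb of an end (right, number of genes). Bars are group means, error bars are SD (n = 3), and points are samples with their replicate numbers. Healthy 1 had 4887 peaks and Healthy 4 had 104501, a range that takes in all IPF values but that of IPF 2.

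Whether samples of the same group shared more accessible sequence depended on the samples included. The Jaccard index, shared over total covered base pairs, averaged 0.278 over 6 pairs within groups and 0.251 over 9 pairs between groups. The difference of 0.0264 was reached by 3 of the 10 splits of the 6 samples (exact one-sided permutation p = 0.3). The sign turned to -0.00817 when sharing was scaled to the shorter list, and to -0.0479, -0.0571 and -0.0579 without IPF 1, 2 and 3. The difference was 0.0336, 0.0990 and 0.189 without Healthy 1, 2 and 4. Among 5 lists of equal length, the index was 0.459 within and 0.422 between groups, and 2 of 10 splits gave as large a difference.

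Merging the peaks of all samples gave 163224 regions. Of these, 4110 had a peak in the 3 IPF samples and in no Healthy sample, and 2 had a peak in the 3 Healthy samples and in no IPF sample. The Healthy-only regions lay on chromosome 4 (142615403 to 142615602), assigned to the phosphoinositide phosphatase gene INPP4B, and on chromosome 6 (52570498 to 52570655), assigned to TRAM2, which takes part in collagen synthesis. The model of list lengths predicted 3113 IPF-only regions, so the observed number was 1.32 times the expected one (95% interval 1.28 to 1.36, chromosome bootstrap). This ratio ranked 7 among the 20 combinations of 3 samples. Of those ranked higher, Healthy 2, Healthy 4 and IPF 2 together held 1355 regions (1.85 times the expected number). The others ranked higher all included Healthy 1 and held at most 31 regions each. The expected number of Healthy-only regions was 0.310. The median position of IPF-only regions in the ranking by −log10 q of the own list was the 34.5th, 46.6th and 35.5th percentile in IPF 1, 2 and 3. Regions shared by all 6 samples stood at the 90.1th, 94.0th and 91.8th percentile, and other regions found in exactly 3 lists at the 31.2th, 42.3th and 32.9th. The count of 4110 depended on Healthy 4, without which it was 23438. It was 10356 without IPF 1 and 8240 without IPF 3. The count of 2 rose to 672 without Healthy 1, and was 15 without Healthy 2, 4 without Healthy 4 and 22 without IPF 2.

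Among 5 lists of equal length, both directions exceeded expectation. Equal lengths tend to balance the 2 directions by construction, so their similarity there carries little information on gains against losses. Among the 42514 strongest peaks of each of the 5 samples other than Healthy 1, 1593 regions were IPF-only and 2076 were Healthy-only. These were 1.71 times (95% interval 1.64 to 1.77) and 1.68 times (1.58 to 1.77) the numbers expected from list lengths. Each was the highest ratio among the 10 patterns with as many samples. The intervals come from draws of chromosomes with the samples held fixed, so they hold no variation between donors. For both directions together the ratio was 1.69. The 9 other divisions into 3 and 2 samples reached at most 1.13 (exact permutation p = 0.1, the smallest possible). Healthy-only regions here need peaks in 2 lists, and IPF-only regions in 3. Healthy 2 kept its whole list, down to a −log10 q of 1.01, while the IPF lists were cut at 2.52 to 3.98. Without the cut these 5 lists gave 4129 IPF-only and 672 Healthy-only regions. Many of the 2076 can therefore reflect weaker IPF peaks that the cut removed. With all 6 lists limited to 4887 peaks, 157 regions were IPF-only (2.43 times the expected number) and 48 Healthy-only (0.744 times), a quotient of 3.27 (2.51 to 4.65). Every combination of 3 samples that included Healthy 1 fell below expectation (0.263 to 0.790 times), so this quotient rests on that list. For both directions together the ratio was 1.59, and the highest other division reached 1.33.

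**Figure D2:**
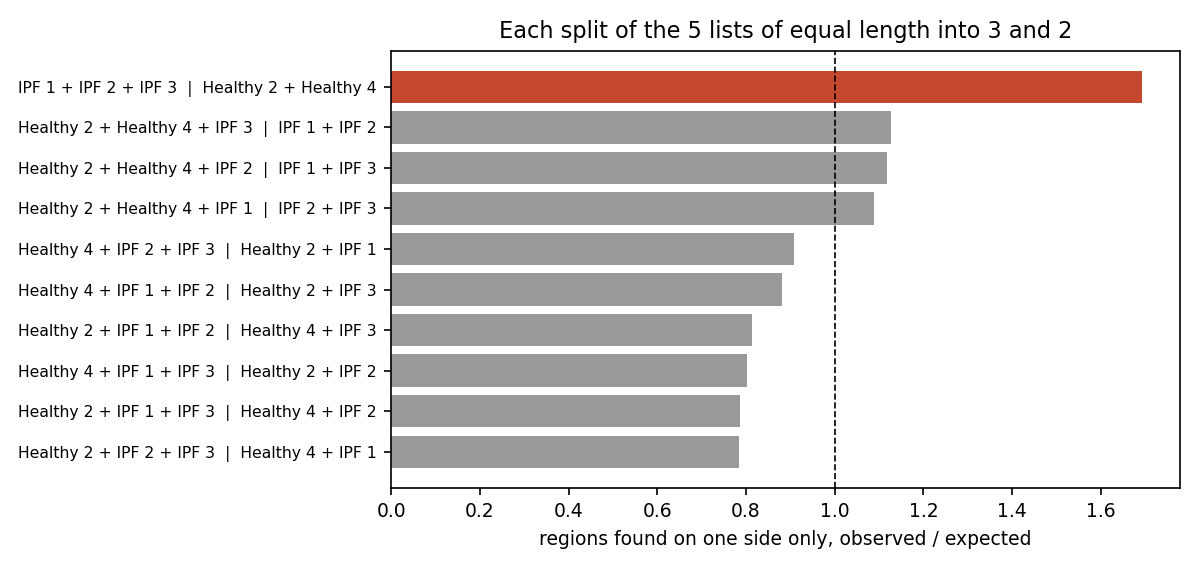
Observed over expected number of regions (x axis, ratio) with a peak in all samples of one side and in none of the other, for each division of the 5 lists of 42514 peaks into 3 and 2 samples (y axis). The division into IPF and Healthy, in red, stood at 1.69, and the highest of the others at 1.13. The dashed line marks a ratio of 1.

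The gene with the most IPF-only regions was SHANK2, which encodes a scaffold protein of the postsynaptic density. It lies on chromosome 11 (70467854 to 71253234, hg38) and was assigned 19 IPF-only regions among 29 background regions, where 1.46 were expected. Of the 19 regions, 18 lay inside the gene, and together they spanned 869 kb. Inside SHANK2, IPF 1, 2 and 3 had 32, 34 and 36 peaks, and Healthy 1, 2 and 4 had 0, 4 and 9. The means were 34 ± 2 and 4.33 ± 4.51 peaks (SD, n = 3 each). Per 10000 peaks of a list this was 3.61 ± 0.764 in IPF and 0.601 ± 0.522 in Healthy (SD, n = 3 each). SHANK2 was picked for regions with peaks in all IPF and no Healthy lists, so the direction of these differences follows from that choice. Their p-values would carry no information and are not given. At equal list length IPF 1, 2 and 3 had 14, 9 and 15 peaks in SHANK2, and Healthy 2 and 4 had 4 and 3. SHANK2 then held 3 IPF-only regions among 10 background regions (0.409 expected), all 3 within the 19, and did not pass the exact binomial scan described below (adjusted p = 1).

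**Figure D3:**
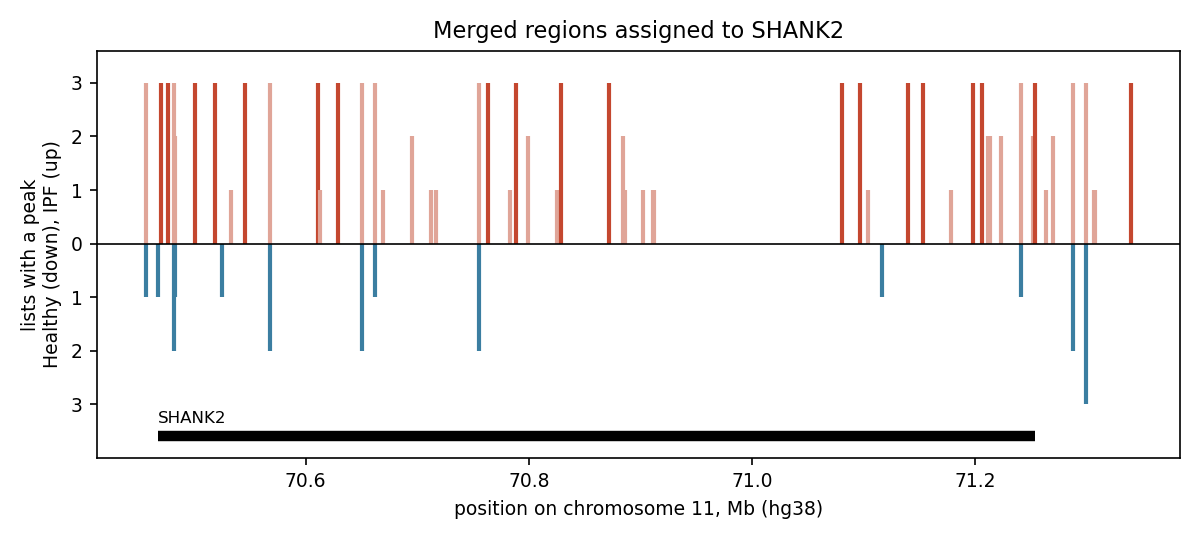
Merged regions assigned to SHANK2 along chromosome 11 (x axis, Mb, hg38). The height of each line is the number of lists with a peak, IPF upward and Healthy downward (0 to 3 each). Dark red lines are the 19 IPF-only regions, and the black bar is the gene.

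The next genes by count of IPF-only regions mostly did not pass that scan. PALLD, encoding the actin-associated protein palladin, held 7 IPF-only regions of 39 background regions (1.96 expected). MYH9, encoding a non-muscle myosin heavy chain, held 6 of 21 (1.05 expected). RBPJ, the DNA-binding effector of Notch signalling, held 6 of 41, the cyclic AMP phosphodiesterase gene PDE4D 6 of 42, SASH1 6 of 30, NAV2 6 of 64 and LRMDA 7 of 45. HPSE2, related to heparanase, held 6 of 13 and C1orf87 5 of 7. In an exact one-sided binomial test over regions, chosen after the region counts had been seen, 5 of 4869 genes passed a Benjamini-Hochberg adjusted threshold of 0.05. By this exact test they were SHANK2 (adjusted p = 1.23e-14), C1orf87 (0.0150), HPSE2 (0.0328), CYP2J2 (0.0330, 4 of 5 regions) and ADAMTS19 (0.0330, 5 of 9 regions). CYP2J2 and C1orf87 are neighbours on chromosome 1. These p-values treat regions as independent and do not measure variation between donors. SHANK2 alone passed without Healthy 4 or without IPF 3. Besides SHANK2, C1orf87 alone passed without Healthy 2 or without IPF 2, so that 1, 1, 2 and 2 genes passed in these 4 settings. In the Healthy direction 0 genes passed, and without Healthy 1 there were 2, GPRC5C and TMEM233.

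At equal list length the genes with the most IPF-only regions were FRMD4A (4 of 28 background regions), C1orf87 (3 of 3), PUS7 (3 of 6), the tetraspanin gene CD9 (3 of 7) and SUFU (3 of 8), an inhibitor of hedgehog signalling. CACNA2D1, EBF1, INPP4B, SHANK2 and SIPA1L1 had 3 of 10 each. Healthy-only regions were most numerous at SLC14A2, which encodes a urea transporter (7 of 20), and at UGT2B4, which encodes a glucuronosyltransferase (4 of 5). ZMAT4 held 4 of 9, the calcium channel gene ITPR1 4 of 12, ZFAT 4 of 13 and COL5A2, a chain of type V collagen, 4 of 17. HIVEP3 held 4 of 19, DLG2 4 of 21, RBPJ 4 of 24 and RAD51B 4 of 36. RBPJ thus had 6 IPF-only regions in the full lists, and none at equal length. In the binomial scan at equal length, none of 1800 genes passed in the IPF direction and 2 of 2785 passed in the Healthy direction, SLC14A2 and UGT2B4 (adjusted p = 0.0173 each). In the same samples without the cut to equal length, neither passed, and GPRC5C and TMEM233 did.

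At gene ends, 121 genes had a peak in the 3 IPF samples and in no Healthy sample, and 0 genes had the reverse. The highest ranked by peak fold within the IPF lists were DIABLO, encoding a mitochondrial activator of apoptosis, and SASH1, encoding a signalling scaffold. MEX3D, FAM131B, SERINC2, the tendon transcription factor gene SCX, SYNE3, AHNAK2, SLFNL1 and BUB1B-PAK6 followed. In 5 of these 10 genes a Healthy peak lay within 100 bp of the window that held the IPF peaks, so the difference there depends on the window's edge. At DIABLO (chromosome 12, 122207662 to 122227456) that distance was 18 bp in both Healthy 2 and Healthy 4. The same holds for MEX3D (77 bp), FAM131B (8 bp), SERINC2 (12 bp) and SCX (31 bp), all in Healthy 4. At SASH1 (chromosome 6, 148193468 to 148552044) the nearest peaks of Healthy 2 and Healthy 4 lay 14570 and 29048 bp outside the window that held the IPF peaks, and SASH1 kept its 3 IPF and 0 Healthy peaks at equal list length. BUB1B-PAK6 is a read-through gene that overlaps its neighbours, so its peak cannot be assigned to it alone. At equal list length 77 genes had an end peak in the 3 IPF samples alone and 164 in Healthy 2 and 4 alone. In the same samples without the cut to equal length, these counts were 121 and 13. The count of 121 was 1731 without Healthy 4, 304 without IPF 1 and 211 without IPF 3, and the count of 0 became 13 without Healthy 1 and 1 without IPF 2.

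The matrix, contractile and protease lists had higher mean numbers of genes with an end peak in IPF, by amounts within the spread between Healthy samples. Over all genes the mean was higher in IPF as well (12441 and 8185). Single members varied, and COL3A1 had an end peak in 0 IPF samples and 1 Healthy sample. Of 22 extracellular matrix genes, 19.0 ± 1.00 had a peak at an end in IPF and 12.7 ± 8.50 in Healthy (SD, n = 3 each). COL6A1, COL6A2, THBS1 and CTHRC1 had one in 3 IPF samples and 1 Healthy sample. Of 15 contractile and myofibroblast genes, 10.3 ± 1.53 and 6 ± 5 had one, with MYL9, ACTG2 and ITGA11 in 3 IPF samples and 1 Healthy sample. Of 19 matrix proteases and inhibitors, 17.0 ± 1.00 and 8.67 ± 8.50 had one, among them ADAM12, CTSK and FAP in 3 IPF samples and 1 Healthy sample. FAP, a marker of activated fibroblasts, had a peak in the 3 IPF samples and in neither Healthy sample at equal length. At equal length the means were 16.3 in IPF and 14.5 in Healthy for matrix, 7 and 6 for contractile, and 11.3 and 10 for protease genes. No list of the 18 had all IPF samples above all Healthy samples. The lowest adjusted p over the 18 lists was 0.45 (exact two-sided permutation, n = 3 each, Benjamini-Hochberg), and 0 lists had an unadjusted p under 0.05. At equal length every list's adjusted p was 1. Without Healthy 4, 16 lists had all IPF samples above both Healthy samples, and without IPF 1 or IPF 3 this held for 2 lists.

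Signalling lists had higher means in IPF in the full lists, with no adjusted p under 0.45, and lower means in IPF at equal length. Of 22 genes of TGF-beta and BMP signalling, 17.7 ± 0.577 had a peak at an end in IPF and 11 ± 8.72 in Healthy (SD, n = 3 each). TGFB2 and INHBA had one in 3 IPF samples and 1 Healthy sample. Of 20 WNT genes, 14.3 ± 1.53 and 8.67 ± 6.81 had one. Of 22 growth factors and receptors, 19.7 ± 1.53 and 10.0 ± 8.54 had one, and FGF10 had one in 3 IPF samples and in no Healthy sample. Of 21 cytokine and inflammation genes, 15.3 ± 4.51 and 9.67 ± 9.02 had one, with CSF2 in 3 IPF samples and no Healthy sample. Of 17 senescence and cell cycle arrest genes, 15.3 ± 0.577 and 9.67 ± 6.81 had one, with the cell cycle inhibitor gene CDKN1A in 3 IPF samples and no Healthy sample. FGF10, CSF2 and CDKN1A had no end peak in any sample at equal length. Of 15 prostaglandin pathway genes, 11.3 ± 0.577 and 7.33 ± 5.03 had one. At equal length the means in IPF and Healthy were 14.7 and 15 for TGF-beta and BMP, 9.33 and 11 for WNT and 10 and 10.5 for growth factor genes. They were 7.67 and 9.5 for cytokine, 10 and 11 for senescence and 8.33 and 8.5 for prostaglandin genes.

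Transcription factor genes that pattern the lung mesenchyme were open at an end in 24.0 ± 2.65 of 28 cases in IPF and 13.7 ± 12.1 in Healthy (SD, n = 3 each). TBX5, FOXF2 and FOXP2 had a peak in 3 IPF samples and 1 Healthy sample, and RUNX1 in 2 IPF samples and 0 Healthy samples. HOX genes, which set position along the body axis, were open in 14.7 ± 4.16 and 7 ± 7.55 of 39 cases, with HOXB7 and HOXB8 in 3 IPF samples and 1 Healthy sample. At equal length both lists turned, with means of 14.7 in IPF and 15 in Healthy for the lung mesenchyme list and 3.67 and 4.5 for HOX genes. There the HOXA2, IL33 and CCN1 ends had peaks in both Healthy samples and in no IPF sample, while FAP and the epithelial genes FOXJ1 and ELF3 showed the reverse. In the full lists HOXA2, IL33 and CCN1 had end peaks in 2, 1 and 3 IPF samples, and in 2 Healthy samples each. FAP, FOXJ1 and ELF3 had them in 3 IPF samples and 1 Healthy sample each. The cut to equal length thus removed peaks that made these ends look particular to 1 group. These 6 genes were picked after their values had been seen.

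Control lists, which hold genes used by every cell or by other cell types, had higher means in IPF as well in the full lists, except the mesothelial list. Of 25 housekeeping genes, 21.3 ± 0.577 had a peak at an end in IPF and 15.0 ± 11.3 in Healthy (SD, n = 3 each), since Healthy 1 had 2, Healthy 2 had 21 and Healthy 4 had 22. Of 25 genes of other organs, 3.67 ± 1.53 and 1.33 ± 1.53 had one, among them the neuronal gene GAD1 in 3 IPF samples and no Healthy sample. Markers of other lung cell types were open in 8.33 ± 2.31 and 3.67 ± 4.04 of 23 epithelial genes, 3.33 ± 0.577 and 1.67 ± 2.08 of 15 endothelial genes, and 6 ± 1 and 3.67 ± 3.06 of 18 immune genes. For 10 pericyte and vascular smooth muscle genes the values were 5.67 ± 0.577 and 3.33 ± 2.52, and for 9 mesothelial genes 2.00 ± 1.00 and 2.67 ± 2.52. The surfactant gene SFTPB had a peak in 3 IPF samples and no Healthy sample, and in no sample at equal length. At equal length IPF means were below Healthy means for housekeeping (18.3 and 19.5), endothelial (1.33 and 1.5), pericyte (2.33 and 2.5), mesothelial (1.33 and 2.5) and other-organ genes (1.33 and 1.5). They stayed above for epithelial (3.67 and 2.5) and immune genes (4.33 and 3.5).

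No list passed the test for more or fewer IPF-only or Healthy-only regions near its genes. LTBP1, LTBP2, TGFBR3 and SMAD3 held 4, 3, 2 and 2 of the 16 IPF-only regions of the TGF-beta and BMP list, where random genes matched on background regions gave 11.6. The growth factor list held 17 (11.9 for random genes), including 3 at IGF1R, 2 at MET and 2 at FGF10. Lung mesenchyme transcription factors held 18 (23.05), including 3 each at FOXF1 and RUNX1. Counts were 12 (14.4) for extracellular matrix, 8 (4.65) for cytokines, 5 (5.06) for senescence, 4 (8.23) for WNT, 3 (4.91) for proteases, 2 (4.95) for contractile, 2 (3.79) for prostaglandin and 1 (1.85) for HOX genes. They were 4 (2.85) for housekeeping, 3 (1.91) for other organs, 2 (4.47) for endothelial, 2 (1.87) for pericyte, 2 (0.759) for mesothelial, 1 (2.20) for epithelial and 0 (1.23) for immune genes. The lowest adjusted p over 36 tests was 1, and 0 lists had an unadjusted p under 0.05 (two-sided permutation of matched genes). Each Healthy-only count was 0. At equal length the lowest adjusted p was 0.941, and 1 list had an unadjusted p under 0.05. This was senescence with 6 IPF-only regions (2.09 for random genes, permutation p = 0.0434), 2 of them at IGFBP7. Simulated lists with a 2-fold excess were called in 27.5% of cases and those with a 3-fold excess in 73.1%. In these simulations all 18 lists were raised at once and adjusted over 18 tests. The shares are therefore too high for a single raised list among 36 tests.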

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

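The tests on gaps of 500 bp, on Healthy 4 as the sole control and on the upper part of each list were chosen after the results were seen, as was the count of genes with a cluster of group-only regions. Group differences in peak number, covered length and share of peaks at gene ends kept their direction under every alternative run, but their size changed (3 against 3 samples allow no exact p under 0.1). With 6 and 5 lists of equal length, covered length fell from 12.6 to 0.635 and 1.93 Mb and the share from -8.84 to -1.54 and -0.917 points, and at the stricter threshold the values were 11978 peaks, 4.51 Mb and -2.21 points. Leaving out each sample gave 23990 to 73797 peaks, 6.82 to 20.1 Mb, -13.7 to -3.53 points and 1134 to 6536 genes with an end peak. No gene list passed near group-only regions in any alternative run. Peak number is fixed when lists have equal length and has no value there. The difference in genes with an end peak turned to -75 genes with 6 and to -334 with 5 lists of equal length. The overlap difference turned to -0.00817 for overlap scaled to the shorter list. IPF-only regions numbered 794 at a −log10 q of at least 5, 157 and 1593 with 6 and 5 lists of equal length, 1485 in bins of 500 bp, 15417 for 2 of 3 samples and 365 in the upper part of each list. Healthy-only regions numbered 0, 48, 2076, 0, 686 and 0 in the same order, 1 with regions 50% covered, 1 with gaps joined and 17092 against Healthy 4 alone. Genes with end peaks in all IPF and no Healthy lists numbered 22 and 77, and the reverse 31 and 164, with 6 and 5 lists of equal length. Genes with a cluster of IPF-only regions numbered 0 at the stricter threshold, with 6 or 5 lists of equal length and in bins, and 2 with regions 50% covered or for 2 of 3 samples. Clusters of Healthy-only regions numbered 2 with 5 lists of equal length and 2 for 2 of 3 samples. Leaving out each sample gave 4129 to 23438 IPF-only and 2 to 672 Healthy-only regions, 121 to 1731 and 0 to 13 end-peak genes, 1 to 5 and 0 to 2 clustered genes, 0 to 16 lists with all IPF above all Healthy, and an overlap difference of -0.0579 to 0.189 (-0.0479 and -0.0571 without IPF 1 and 2). With few samples and fewer peaks some movement follows by construction, and otherwise the cause was not tested.

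Only numbers 1 and 2 occur in both groups, and they pair no donors. Used as a replicate block, they gave 32545 IPF-only and 6 Healthy-only regions, 2007 end-peak genes, 0 genes with a cluster and 16 lists with all IPF above all Healthy. Among named genes, MMP10 turned to -33.3 percentage points at the stricter threshold, and PTGS1 and KDR to -50 and -16.7 with 5 lists of equal length. Of 1450 values for named genes, these 3 included, 891 stayed within 1.5 times or 34 points, 556 moved and 3 turned. Leaving out a sample or using the replicate block cannot move the end peaks of a named gene by 34 points. All 58 genes with such values therefore stayed in those settings by construction, which shows no robustness. All alternatives for motifs were not run. Without read counts, a peak absent from a list cannot be told from one under its detection limit.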

Other observations

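The tests below were chosen after the results they address had been seen, except the splits for clustered genes. IPF-only regions lay mostly away from gene ends: 6.23% were within 1 kb of one and 52.8% elsewhere inside a gene, against 6.72% and 49.9% of the 16656 other regions found in exactly 3 lists, and 39.1% and 31.6% of regions in all 6. Of the 4110, 365 were in the upper part of all 3 IPF lists by −log10 q. Ranked by their lowest percentile, the strongest lay inside DAAM1, a formin that builds actin filaments (chromosome 14, 59215377 to 59215667, at least the 89.6th percentile), near SIPA1L1, inside GNB1L and at an end of SASH1 (chromosome 6, 148191902 to 148192756, 87.9th). The nearest Healthy 4 peak was 26.6 kb away at DAAM1, 33.6 kb at SIPA1L1, 15.9 kb at GNB1L and 30.8 kb at SASH1. A SHANK2 region ranked 10 (chromosome 11, 70788319 to 70788635, 83.8th). These genes were picked by this ranking.

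The full lists held 4110 IPF-only and 2 Healthy-only regions. Unequal list lengths are a candidate explanation of most of this imbalance, since the model of list lengths predicted 75.7% of the IPF-only regions (73.4 to 78.4%). The model takes the number of regions found in 3 lists as given, IPF-only ones included, and it understated an added excess. This share may therefore be too high. Whether IPF cultures also gain regions more often than they lose them cannot be told apart from differences in depth. At equal length the IPF ratio to expectation was 1.02 times the Healthy ratio (0.948 to 1.08), but equal lengths tend to balance gains and losses by construction. With Healthy 1 included at 4887 peaks that quotient was 3.27 (2.51 to 4.65), and it then rests on the shortest list. Of the 10 splits of 6 samples, 3 gave as many regions (4112 real, 8615 the highest other) and 3 as many end-peak genes (121 real, 419 the highest other). The highest in both set the 3 shortest lists, Healthy 1, Healthy 2 and IPF 1, against the 3 longest, a structure of list length. At equal length 1 of 10 splits reached the real ratio of 1.69 (1.13 the highest other). So few splits allow no share under 0.05.

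The list of Healthy 1 was 8.70 times shorter than the next. Noise at places particular to that library, as the source of its autosomal peaks, is argued against, because 98.2% of them overlapped a peak of another list. That overlap does not bear on signal from outside open chromatin that recurs between libraries, because such signal would overlap too. Nor does it bear on a high background that hides weaker peaks. Neither was tested. Low sensitivity of the library or of the calling stays open. Of the peaks of Healthy 1, 78.5% lay in regions of all 5 other lists, between the 80% set for it and the 50% set against it. Of 25 housekeeping genes, a reference for sensitivity, 2 had an end peak in Healthy 1 and 21 or 22 in each other list. That goes with low sensitivity, but a lower accessibility or a different processing of that culture was not tested. The lists hold no depth to test sensitivity with. Housekeeping genes were not favoured in Healthy 1, where 10.2% of all genes had an end peak (51.6 to 68.6% in the other lists). At 4887 peaks per list, 2375 regions were found in Healthy 1 alone, against 603 to 1175 in each other list alone. Many of its peaks were thus not among the strongest of the other lists. Healthy 1 alone also held 18 peaks on unplaced or mitochondrial sequences.

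At SHANK2, 19 regions were IPF-only. SHANK2 passed the scan in 8 of 13 alternatives: without each sample in turn, with regions 50% covered and for 2 of 3 samples. It did not pass at the stricter threshold, at either equal length, in bins or in the replicate block. Whether weak regions near the calling threshold account for the cluster cannot be told. Its 19 regions had median percentiles of 41.6, 54.0 and 39.2 in IPF 1, 2 and 3, above the 34.5, 46.6 and 35.5 of all IPF-only regions, and 5 of the 19 were in the upper part of all 3 lists (365 of 4110 overall). Most were thus not in that part, and at the stricter threshold the cluster did not pass. Found without Healthy 4, SHANK2 had 22 IPF-only regions, and Healthy 4 had a peak in 13.6% of them, against 83.5% for IPF-only regions of equal strength. But SHANK2 was picked partly for lacking Healthy 4 peaks and ranked 4 by region number without Healthy 4, so this choice favours a low share. Whether Healthy 4 alone lacks them cannot be told either: of 19 regions found without Healthy 2, that sample had a peak in 0%, where 9.01% was expected, and the same choice favours a low value. Of the splits of 6 samples, the other 9 passed at most 0 genes and the real one 5 (1 of 10 splits). A difference in SHANK2 chromatin between IPF and healthy fibroblasts stays open beside these explanations, and other differences between the donors were not tested.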
